A study of Homo sapiens with 14 samples.

How the data were processed

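The series holds RNA-seq of total RNA from human pluripotent stem cells (H9, WA-09) and from cultures differentiated from them toward midbrain dopamine neurons, 14 libraries in 7 groups of 2. Per the labels, the groups are undifferentiated cells, day 11 cultures with 0.7, 3, 5 or 7.5 µM CHIR99021 from day 4, and day 16 and day 30 cultures of the 7.5 µM protocol. The series text speaks of day 20 where the labels give day 16, and the labels are followed here. The end of the boost is given as day 9 in one place of the records and day 10 in another.

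The values are read counts per gene as deposited by the authors. The submitters' processing notes name STAR 2.4.2a, featureCounts 1.4.2, HTSeq 0.5.3 and DESeq2 1.12.4 and the hg19 genome. The library kit, its strandedness and the counting options are not given in the sources used here. The hPSC and day 11 tables hold 57445 gene entries and 5 summary entries for reads counted to no gene, and the day 16 and day 30 tables hold 57820 gene entries, of which 57230 are shared. The summary entries, 37.41% to 44.33% of all counts in the hPSC and day 11 tables, were left out of library sizes and tests. Gene counts came to 20.5 to 44.8 M in the hPSC and day 11 libraries and to 5.41 to 6.34 M in the later ones. Gene type, strand, length and overlap came from GENCODE 29, joined by gene identifier only; 51812 of the 57230 shared genes had an entry, and no coordinates are reported since its genome build differs.

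Counts were tested with edgeR 4.0.16 (limma 3.58.1, R 4.3.3): TMM scaling, filterByExpr, robust quasi-likelihood fits and F-tests, with Benjamini-Hochberg adjustment and a threshold of 0.05. The day 11 dose comparisons and the slope over log2 concentration used the 8 day 11 libraries (18709 genes). Those against hPSC used these and the hPSC libraries (19672 genes), day 30 against day 16 used its 4 libraries (15435 genes), and day 16 against day 11 used 6 libraries and the genes of both kinds of table (19180 genes). CPM are TMM-scaled within each fit and so differ slightly between comparisons. The replicates are not said to be separate cultures, so the p-values measure only the spread between these libraries.

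Whether replicate numbers pair the libraries was checked from the correlation of same-numbered deviations from the group means across genes. It was 0.66 to 0.87 for the 6 pairs of day 11 groups, −0.11 to −0.18 between hPSC and the day 11 groups, −0.22 between day 16 and day 30 and −0.05 between day 11 and day 16. The pairing at day 11 thus comes from the data; the sample descriptions also carry 1 code for all day 11 replicate 1 libraries and another for all replicate 2 libraries. The rule for pairing (every pair of groups correlated above 0.1) was set beforehand, but the correlations and the counts of calls with and without the block were first seen together. Day 11 results are given without and with the replicate number as a block, and against hPSC also with a block within day 11.

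Gene lists were written from general knowledge before the data were examined, 23 in all: WNT feedback and target genes, midbrain floor plate, midbrain-hindbrain boundary, FGF feedback, hindbrain, telencephalon, diencephalon and hypothalamus, SHH targets, dorsal and roof plate, pluripotency, neural progenitor, Notch pathway, cell cycle, general neuronal, midbrain dopamine neuron, other neuron classes, glia, neural crest, mesoderm and caudal, mesenchymal and vascular, choroid plexus, p53 targets, and hypoxia and glycolysis. Members were counted as passing over all genes and, separately, adjusted over the list alone. Lists with at least 3 tested members were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. The second form takes its reference distribution from the residual degrees of freedom of the fit, 1 to 6 with all libraries. It can lose calls through few libraries alone, so a lost call does not show that list members vary together.

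Genes are named by a fixed rule, and some that it names are not reported here. Part (a) takes the 6 higher and 6 lower genes of largest fold change among those that pass, with at least 5 CPM in the higher group and no overlap of libraries (3 and 3 in the lesser dose comparisons). At day 11 it used the blocked fit, as does the wording of changes in the dose comparisons, a choice made after the fit without the block was seen to call no gene. Part (b) takes up to 4 passing members of each list, and part (c) 25 genes fixed beforehand. Where a group held 0 counts, the bound takes a floor of 3 counts, and for 1 to 3 counts the ratio of counts is given with a 95% interval. Bounds, ratios and intervals are scaled by TMM library size, and no fitted fold change is given for these. The tests without the block, the lists, the naming rule and most alternatives were fixed before the data were examined. The alternatives of the blocked fits, the fit on protein-coding genes with no annotated gene on the other strand within 2 kb and the crossed pairing were added afterwards.

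The tests were tested on simulated data with the depth and spread of each comparison, 100 genes changed 2-fold and 100 changed 4-fold. A simulated list of 15 genes changed 2-fold was called in every fit at the preset correlation (largest camera adjusted p = 0.0419). The form with an estimated correlation was not simulated. Unchanged lists were called 1 time, of 22 in the 0.7 µM fit against hPSC. As simulated genes were independent, this cannot show how often lists whose members vary together are called falsely. Alternatives were RLE and upper-quartile scaling, no filter and a filter of 5 CPM in 2 libraries, DESeq2 1.42.0, each library left out, hPSC libraries in the model, and a linear dose scale. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.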

Results

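RNA was sequenced in 14 libraries, 2 for each of 7 groups, from H9 (WA-09), an established line of human pluripotent stem cells, and from cells derived from it on the way to midbrain dopamine neurons. The groups were undifferentiated stem cells (hPSC), day 11 cultures given the GSK3 inhibitor CHIR99021 (CHIR) at 0.7, 3, 5 or 7.5 µM, and cultures of the 7.5 µM protocol labelled day 16 and day 30. Blocking GSK3 activates WNT signalling, which patterns the neural tube from front to back. Per the labels, all cultures had 0.7 µM CHIR up to day 3, the 4 concentrations were given from day 4, and from day 10 the medium of every arm held 3 µM CHIR. They also had Sonic hedgehog protein, which induces the floor plate, and the compounds LDN and SB, inhibitors of BMP and TGF-beta signalling. The labels give day 7 for the removal of patterning factors, and days 11 and 16 for replating. Gene counts came to 32.29 and 25.06 M in hPSC replicates 1 and 2. At day 11 they were 20.52 and 44.76 M at 0.7 µM, 26.65 and 28.4 M at 3 µM, 20.77 and 34.24 M at 5 µM, and 33.67 and 32.08 M at 7.5 µM. The later tables were shallower, with 6.34 and 5.41 M at day 16 and 5.66 and 5.46 M at day 30. Levels are given as TMM-scaled CPM, mean ± SD (n = 2 in every group). Changes are log2 fold changes. Ratios of counts and lower bounds from a count of 0 (a floor of 3 counts over the group) are scaled by TMM library size. The bounds and the intervals on the ratios cover counting error only, not the scaling.

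At day 11 the libraries numbered replicate 1 differed from those numbered replicate 2 in the same genes in all 4 arms. The correlation of the deviations was 0.66 to 0.87 over the 6 pairs of arms, across 18709 genes, which are not independent replicates. The numbers therefore pair the day 11 libraries, and each day 11 comparison is given without and with the replicate number as a block. In the day 11 dose comparisons "rose", "fell" and "changed" refer to the blocked fit, a choice made after the fit without the block was seen to call 0 genes. In the principal components of the 8 libraries, PC1 (56.8% of the variance) separated replicate 1 from replicate 2 at 0.7, 3 and 5 µM, and the 7.5 µM libraries stood apart from the other arms on PC2 (23%). Replicate 1 at 7.5 µM lay at −1.8 on PC1, between the other replicate 1 libraries (−101.6 to −92.5) and the replicate 2 libraries (65.6 to 81.4).

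**Figure D1:**
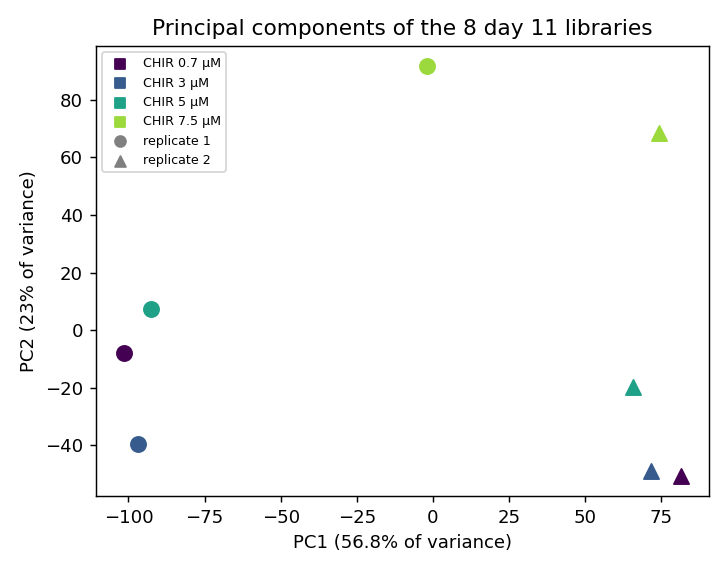
Principal components of log2 CPM in the 8 day 11 libraries; colour gives the CHIR concentration and the symbol the replicate number. PC1 takes 56.8% of the variance and PC2 23%, and the 7.5 µM libraries sit at 91.6 and 68.4 on PC2.

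The day 11 cultures given 7.5 µM CHIR from day 4 were set against those given 0.7 µM, both having had 3 µM from day 10. Genes that WNT signalling induces were far higher after the boost. SP5 (ENSG00000204335), a transcription factor directly induced by WNT, rose to 118 ± 22.9 CPM from 2.20 ± 2.01. So did AXIN2 (ENSG00000168646), a feedback inhibitor of the pathway, to 253 ± 24.8 from 46.9 ± 31.3. EN1 (ENSG00000163064), a transcription factor of the midbrain and anterior hindbrain, rose from 5.68 ± 3.29 to 98.8 ± 20.1 CPM. NKX2-1 (ENSG00000136352), a marker of the ventral forebrain and hypothalamus, fell from 10.9 ± 3.51 to 0.0532 ± 0.0752 CPM. FOXA2 and LMX1A, transcription factors that mark the midbrain floor plate, did not pass the test. FOXA2 stood at 140 ± 99 CPM at 0.7 µM and 80.2 ± 12.8 at 7.5 µM, and LMX1A at 60.8 ± 27.9 and 96.4 ± 7.47.

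Of the 14 WNT feedback and target genes, 10 rose and none fell (12 rose adjusted over the list alone). They include NOTUM, which inactivates WNT proteins (log2 fold change 5.72), APCDD1, a membrane inhibitor of WNT (5.15), and LEF1, the nuclear partner of beta-catenin (2.42). LGR5, a receptor that strengthens WNT signalling, had 222 counts against 1, a ratio of 197 (95% interval 35 to 7810). Camera's adjusted p for the list was 9.39e-22, and adjusted p = 0.0938 with an estimated correlation (0.0204 without the block). In the midbrain-hindbrain boundary list, 6 of 9 tested genes rose and none fell (7 and 1 adjusted over the list alone). FGF17, a signal of the boundary, rose by 5.22, CNPY1, an FGF regulator, by 4.90 and PAX5 by 4.36. EN2 had 266 counts against 1 (ratio 236, interval 42 to 9350). Camera's adjusted p was 1.83e-10, and adjusted p = 0.144 with an estimated correlation. FGF8, the organizer's main signal, did not pass (1.57), and passed without 0.7 µM replicate 2 (2.85). PAX8, an early boundary gene, did not pass (−0.96), and passed without 0.7 µM replicate 1 (−1.60). Of the 9 genes that FGF signalling induces, 8 rose (8 adjusted over the list alone), such as SPRY1 (2.89) and SPRY2 (2.25), feedback inhibitors of FGF receptors (camera adjusted p = 1.55e-07, and adjusted p = 0.28 with an estimated correlation).

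The midbrain floor plate list moved in both directions, with 2 of 12 genes up and 5 down (4 and 6 adjusted over the list alone; camera adjusted p = 0.0237, and adjusted p = 0.432 with an estimated correlation). CORIN, a floor plate protease, fell by 3.35 on the log2 scale. SHH itself passed as lower (−2.36, from 164 ± 160 to 23.7 ± 5.3 CPM), but not without 0.7 µM replicate 1 (−1.30) or without 7.5 µM replicate 1 (−1.51). OTX2, which marks forebrain and midbrain, rose from 109 ± 29.3 to 299 ± 12.4 CPM (1.45), a call lost without 0.7 µM replicate 1 (1.13). The list's call was lost without 0.7 µM replicate 1 (camera adjusted p = 0.172) or 7.5 µM replicate 1 (0.202). FOXA2 passed as lower without 7.5 µM replicate 2 (−1.15) and LMX1A as higher without 7.5 µM replicate 1 (1.08).

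In the telencephalic list 0 rose and 3 of 6 fell (1 and 4 adjusted over the list alone; camera adjusted p = 0.0183, and adjusted p = 0.28 with an estimated correlation). Among them was SIX3, a gene of the anterior neural plate, with 25 counts at 0.7 µM and 3 at 7.5 µM (ratio 9.4, interval 2.87 to 48.6). In the diencephalic and hypothalamic list 1 gene rose and 3 of 9 fell (1 and 5 adjusted over the list alone), led by NKX2-1 at −7.60 (camera adjusted p = 0.00326, and adjusted p = 0.207 with an estimated correlation). Without 7.5 µM replicate 2 the telencephalic and diencephalic lists lost their calls (camera adjusted p = 0.262 and 0.221). Of the roof plate and dorsal neural tube genes 7 of 10 rose and none fell (8 adjusted over the list alone; camera adjusted p = 3.38e-12, and adjusted p = 0.126 with an estimated correlation). ZIC1 stood at 8.31, PAX3 at 4.91 and BMP6, a roof plate signal, at 4.75. Genes of caudal epiblast and mesoderm gave 3 of 7 higher and none lower (4 adjusted over the list alone; camera adjusted p = 2.28e-05, and adjusted p = 0.186 with an estimated correlation). CDX2, a posterior homeobox gene, had 737 counts against 0, at least 218-fold higher, and T (brachyury), the mesodermal transcription factor, 1080 against 1 (ratio 958, interval 172 to 37900). Of 4 hindbrain genes tested, 1 rose (1 and 1 adjusted over the list alone; camera adjusted p = 0.706).

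Among proliferation genes, MKI67, the Ki-67 antigen, rose to 290 ± 60.5 CPM from 89.4 ± 24.3, and CCNB1, cyclin B1, to 180 ± 10.8 from 61.4 ± 14.1. Of 15 cell cycle genes 10 rose and none fell (15 adjusted over the list alone; camera adjusted p = 1.84e-10, and adjusted p = 0.198 with an estimated correlation). Hypoxia and glycolysis genes fell in 5 of 10 cases and none rose (5 adjusted over the list alone), such as EGLN3, an oxygen sensor, by 2.58 (camera adjusted p = 0.000265, and adjusted p = 0.186 with an estimated correlation). That list differs between replicates 1 and 2 as well, with 9 of 10 members higher in replicate 2. In the dopamine neuron list 0 rose and 2 of 11 fell (2 adjusted over the list alone; camera adjusted p = 0.00302, and adjusted p = 0.186 with an estimated correlation). They were DLK1, from 267 ± 211 to 14.6 ± 7.59 CPM, and GFRA1, the GDNF receptor, from 41.5 ± 8.31 to 4.14 ± 0.582. GAD1, the enzyme that makes GABA, was among 2 of 6 genes of other neuron classes that rose (4.24; 3 and 1 adjusted over the list alone; camera adjusted p = 0.0289, and adjusted p = 0.285 with an estimated correlation). Neural progenitor genes gave 1 of 12 higher and 3 lower (1 and 3 adjusted over the list alone), among them MSI1, an RNA-binding protein of progenitors (−0.94; camera adjusted p = 0.0446, and adjusted p = 0.254 with an estimated correlation). The call of the list of other neuron classes was lost without 0.7 µM replicate 1 (camera adjusted p = 0.107), 7.5 µM replicate 1 (0.158) or 7.5 µM replicate 2 (0.0618). That of the progenitor list was lost without 0.7 µM replicate 1 (camera adjusted p = 0.0852) or 7.5 µM replicate 2 (0.0618). SOX2 did not pass (−0.59), and passed without 7.5 µM replicate 1 (−1.08).

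Among genes of any kind, the rule for named genes also gave EGFLAM, an extracellular matrix protein (6.35), ZIC4 (6.25) and TAL2, a transcription factor of midbrain GABA neurons (6.23), as higher. On the lower side it gave GPR4, a proton-sensing receptor (−5.30), DCC, the netrin receptor (−5.23), PAX6, a forebrain and progenitor transcription factor (−5.03), and ADAM33, a metalloprotease (−4.59). TUBB3 (neuronal tubulin) and NR4A2 (a dopamine neuron transcription factor) did not pass (0.20 and 0.25), though TUBB3 passed as higher without 7.5 µM replicate 2 (0.70).

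With edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 0 of 18709 genes passed without the block (1641 at an unadjusted p under 0.05, 657 by DESeq2) and 1967 with it, 1056 higher and 911 lower (5406 and 3006). For SP5 the blocked estimate was 5.65 with a standard error of 0.59 (edgeR adjusted p = 0.000789), for AXIN2 2.57 with 0.33 (0.00177), for EN1 3.95 with 0.58 (0.00351) and for MKI67 1.71 with 0.24 (0.00258). The count was 754 without 0.7 µM replicate 1, 822 without 0.7 µM replicate 2 and 5613 without 7.5 µM replicate 2. In simulated data for this comparison the unblocked test called 0 of 100 genes changed 4-fold. The blocked test called 85 of 100 changed 4-fold and 16 of 100 changed 2-fold, with 9 false calls among 112. That simulation gave all arms the same replicate difference, while 7.5 µM replicate 1 shares it only in part on PC1. It therefore cannot show how the blocked test fares in these data.

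**Figure D2:**
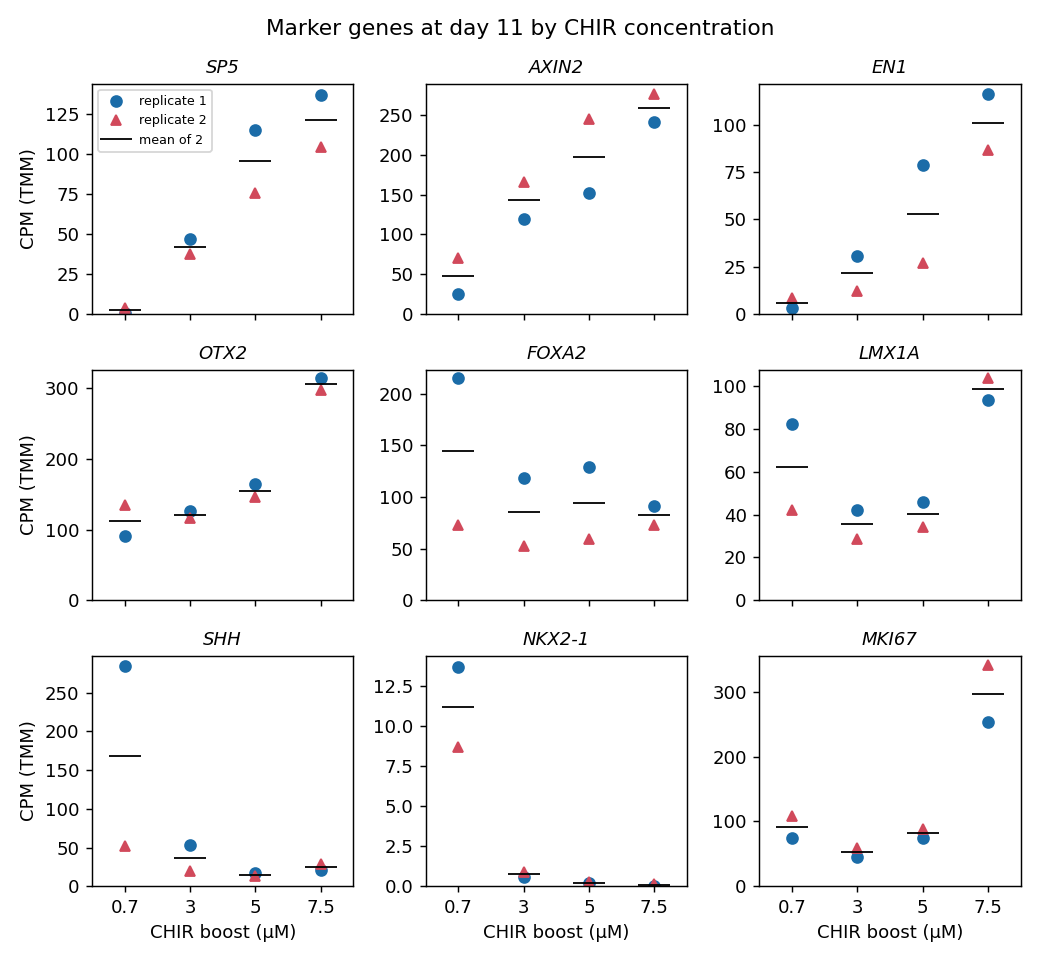
Levels of 9 marker genes in the 8 day 11 libraries (CPM on linear axes, scaled over the hPSC and day 11 libraries) by CHIR concentration; points are the 2 replicates and bars their mean. SP5 averages 2.26, 42, 95.6 and 121 CPM from 0.7 to 7.5 µM, and MKI67 91.7, 52.5, 82.1 and 297.

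At 5 µM against 0.7 µM, WNT target genes were again higher: SP5 stood at 93.1 ± 27.3 CPM, LEF1 at 156 ± 12.9 against 34 ± 15.5, and NOTUM at 35.2 ± 3.29 against 0.432 ± 0.213. NKX2-1 was down to 0.206 ± 0.0519 CPM and DCC to 2.26 ± 0.415 against 65.9 ± 40.1. Of 15 cell cycle genes 0 passed (0 adjusted over the list alone; camera adjusted p = 0.138, and 0.028 without 0.7 µM replicate 2 or 0.0183 without 5 µM replicate 2), and MKI67 stood at 79.9 ± 9.44 CPM against 89.4 ± 24.3. With an estimated correlation the list had adjusted p = 0.639, and 0.414 and 0.432 without those libraries. FOXA2 (−0.54), LMX1A (−0.59) and OTX2 (0.47) did not pass either.

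Of the 14 WNT genes 7 rose at 5 µM and none fell (9 adjusted over the list alone), with NOTUM at 6.46, SP5 at 5.31 and DKK1, a secreted WNT antagonist, at 3.93 (camera adjusted p = 1.66e-31, and adjusted p = 0.0779 with an estimated correlation). The floor plate list had 0 up and 5 of 12 down (1 and 7 adjusted over the list alone), such as CORIN (−3.50) and the axon guidance gene NTN1 (−2.33; camera adjusted p = 8.75e-10, and adjusted p = 0.121 with an estimated correlation). CORIN lost its call without 0.7 µM replicate 1 (−2.87), 5 µM replicate 1 (−3.64) or 5 µM replicate 2 (−3.39). In the boundary list 2 of 9 rose (7 adjusted over the list alone; camera adjusted p = 1.76e-11, and adjusted p = 0.0779 with an estimated correlation). They were EN1, by 2.90, a call lost without 0.7 µM replicate 1 (1.96) or 5 µM replicate 1 (2.25), and FGF17, by 4.92, lost without 0.7 µM replicate 1 (4.39). Dorsal genes gave 3 of 10 higher (5 adjusted over the list alone), among them ZIC1 (4.75) and PAX3 (3.84; camera adjusted p = 3.52e-09, and adjusted p = 0.0779 with an estimated correlation). Caudal and mesodermal genes gave 2 of 7 higher (4 adjusted over the list alone; camera adjusted p = 3.89e-12, and adjusted p = 0.0779 with an estimated correlation). CDX2 stood at 357 counts against 0, at least 145-fold higher. CA4, a carbonic anhydrase, was the other leading gene on the higher side (6.09). HHIP, which binds and restrains hedgehog proteins, was among those on the lower side (−5.37), a call lost without 0.7 µM replicate 1 (−4.33) or 5 µM replicate 1 (−4.83). Without the block, edgeR's quasi-likelihood test called 0 of 18709 genes (567 at an unadjusted p under 0.05, 129 by DESeq2). With it, 211 passed, 132 higher and 79 lower (1893 and 612). That count was 50 without 0.7 µM replicate 1, 60 without 5 µM replicate 1 and 95 without 5 µM replicate 2.

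At 3 µM against 0.7 µM few genes passed. NOTUM rose (5.15, from 0.432 ± 0.213 to 16.1 ± 11.5 CPM), as did ADRA2C, an adrenergic receptor (3.18), and GPC3, a glypican that modulates WNT and hedgehog signals, fell by 2.64 on the log2 scale. SP5 (4.13), LEF1 (1.51), AXIN2 (1.68), EN1 (1.62) and NKX2-1 (−3.92) did not pass. Of the 14 WNT genes 1 rose (9 adjusted over the list alone; camera adjusted p = 3.9e-24, and adjusted p = 0.112 with an estimated correlation). Of 12 floor plate genes 0 passed (1 up and 7 down adjusted over the list alone; camera adjusted p = 8.93e-09, and adjusted p = 0.175 with an estimated correlation). CDX2, with 58 counts against 0 (at least 26-fold), and T, with 23 against 1 (ratio 30.9, interval 5.01 to 1270), did not pass. The blocked edgeR quasi-likelihood test called 4 genes, 3 higher and 1 lower (1400 at an unadjusted p under 0.05, 196 by DESeq2), of which the rule names NOTUM, ADRA2C and GPC3. Without the block it called 0 (276 and 17). NOTUM (5.30) and ADRA2C (3.40) lost their calls without 0.7 µM replicate 1, and GPC3 without 0.7 µM replicate 1 (−2.28) or 3 µM replicate 1 (−2.50). Leaving out each library in turn gave between 0 and 59 calls.

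Across the 4 concentrations, a slope per doubling of CHIR was fitted to all 8 day 11 libraries, and the slopes that follow are those without the block unless it is named. NKX2-1 fell by 2.08 per doubling, and SP5 rose by 1.75 and CA4 by 1.88. T and CDX2 also passed, with 1080 and 737 counts at 7.5 µM against 1 and 0 at 0.7 µM. LRRN3, a leucine-rich repeat membrane protein, and DPP6, a subunit of potassium channels, had slopes of −1.14 and −1.11. LEF1 (0.72), AXIN2 (0.71) and EN1 (1.18) did not pass without the block and passed with it (0.74, 0.75 and 1.13). Without the block, 1 of 14 WNT genes (8 adjusted over the list alone), 2 of 7 caudal and mesodermal genes (4) and 1 of 10 dorsal genes (5) passed with a positive slope, and with the block 7 (10), 2 (4) and 4 (5). The WNT (camera adjusted p = 0.000961), mesodermal (0.0111), telencephalic (0.0193) and midbrain-hindbrain boundary (0.046) lists held with an estimated correlation in the fit without the block, as did the diencephalic, SHH, dorsal, progenitor and dopamine neuron lists (0.0471 each). Of these the telencephalic, diencephalic, SHH, progenitor and dopamine neuron lists went down. With the block the SHH and dopamine neuron lists no longer held with an estimated correlation (camera adjusted p = 0.0619 each). At the preset correlation the diencephalic (camera adjusted p = 0.0527) and dopamine neuron (0.064) lists lost their calls without 0.7 µM replicate 2, and the progenitor list without 0.7 µM replicate 1 (0.152). By edgeR's quasi-likelihood test 25 genes had a slope, 15 up and 10 down (1106 at an unadjusted p under 0.05, 330 by DESeq2), and 222 with the block, 135 up and 87 down (2251 and 812). Without the 7.5 µM arm the counts were 0 and 919, and without 0.7 µM replicate 1 the blocked count was 2. The unblocked calls of SP5 and CDX2 were lost whichever library was left out. In simulated data for the slope, the blocked fit made 7 false calls among 58.

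Between neighbouring concentrations, 5 µM against 3 µM gave no gene past the threshold. SP5 (1.19), EN1 (1.28), LEF1 (0.75), AXIN2 (0.45) and NKX2-1 (−1.76) all missed it. Of the 14 WNT genes 0 passed over all genes and 2 rose adjusted over the list alone (camera adjusted p = 1.27e-08, and adjusted p = 0.148 with an estimated correlation). The mesodermal list (camera adjusted p = 1.66e-11, and adjusted p = 0.148 with an estimated correlation) and the cell cycle list (2.65e-09, and adjusted p = 0.189 with an estimated correlation) leaned upward. The blocked edgeR quasi-likelihood test called 0 genes (527 at an unadjusted p under 0.05, 33 by DESeq2), and the unblocked test 0 (101 and 0). In simulated data for this comparison the blocked test called 87 of 100 genes changed 4-fold and 16 of 100 changed 2-fold.

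From 5 to 7.5 µM, MKI67 went from 79.9 ± 9.44 to 290 ± 60.5 CPM (1.85), and 8 of 15 cell cycle genes rose with none lower (12 adjusted over the list alone; camera adjusted p = 1.96e-08, and adjusted p = 0.578 with an estimated correlation). LMX1A rose from 39.1 ± 7.87 to 96.4 ± 7.47 CPM (1.35), and ZIC1 from 4.48 ± 2.75 to 52.1 ± 28.8 (3.56). SP5 (0.34), LEF1 (0.17), AXIN2 (0.45), EN1 (1.05), FOXA2 (−0.05) and OTX2 (0.98) did not pass, and OTX2 passed without 7.5 µM replicate 2 (1.04). Hypoxia genes fell in 5 of 10 cases (7 adjusted over the list alone), among them NDRG1, a hypoxia-induced gene, by 3.49 (camera adjusted p = 1.96e-08, and adjusted p = 0.326 with an estimated correlation).

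Dorsal genes gave 4 of 10 higher from 5 to 7.5 µM (7 and 1 adjusted over the list alone; camera adjusted p = 9.44e-05, and adjusted p = 0.439 with an estimated correlation). Boundary genes gave 3 of 9 (3 adjusted over the list alone; camera adjusted p = 0.0222, and adjusted p = 0.772 with an estimated correlation), led by CNPY1 (3.48). Of the WNT genes 3 of 14 rose (3 adjusted over the list alone; camera adjusted p = 0.0367, and adjusted p = 0.772 with an estimated correlation), including APCDD1 (2.49). P53 targets gave 0 higher and 3 of 12 lower (5 adjusted over the list alone; camera adjusted p = 0.0244, and adjusted p = 0.772 with an estimated correlation). The WNT list lost its call without 5 µM replicate 2 (camera adjusted p = 0.0908), 7.5 µM replicate 1 (0.105) or 7.5 µM replicate 2 (0.238), and the boundary list without the same libraries (0.174, 0.153 and 0.0855). The p53 list lost it without 7.5 µM replicate 2 (camera adjusted p = 0.958). GPR4 (−4.94) and GRM4, a glutamate receptor (−4.41), led the lower side. The blocked edgeR quasi-likelihood test called 1221 genes, 603 higher and 618 lower (5323 at an unadjusted p under 0.05, 2777 by DESeq2). The unblocked test called 0 (1168 and 203). In simulated data for this comparison the blocked test made 16 false calls among 127. The blocked count was 30 without 5 µM replicate 1, 5 without 5 µM replicate 2 and 5828 without 7.5 µM replicate 2. The calls of MKI67 (1.96 and 1.68), LMX1A (1.32 and 1.31), APCDD1 (2.33 and 2.60), CNPY1 (3.09 and 3.78) and NDRG1 (−3.41 and −3.57) were lost without either 5 µM library, and those of ZIC1 (3.28) and GPR4 (−4.77) without 5 µM replicate 2.

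Day 11 cells at 7.5 µM were set against the undifferentiated stem cells to see what the protocol had turned on and off. POU5F1 (OCT4), the central pluripotency factor, fell from 443 ± 43.6 to 0.382 ± 0.0779 CPM, TDGF1, a Nodal co-receptor, by 11.00 on the log2 scale, and NANOG from 1169 to 2 counts. Floor plate genes came on: LMX1A rose from 0.104 ± 0.109 to 98.9 ± 7.49 CPM, FOXA2 from 0.303 ± 0.274 to 82.3 ± 13.2 and OTX2 from 20.1 ± 2.35 to 306 ± 13.3. EN1 had 7431 counts against 2 (ratio 3240, interval 895 to 26700). SOX2, shared by stem cells and neural progenitors, did not pass (−0.27).

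Of 12 floor plate genes 11 rose and none fell (12 adjusted over the list alone; camera adjusted p = 6.45e-21, and adjusted p = 0.0341 with an estimated correlation), FOXA1 by 9.48 and SHH by 8.53. Pluripotency genes gave 0 higher and 9 of 13 lower (9 adjusted over the list alone; camera adjusted p = 3.34e-14, and adjusted p = 0.0341 with an estimated correlation). LIN28A, an RNA-binding protein of stem cells and early progenitors, did not pass (−0.20), at 1440 ± 338 CPM in hPSC and 1250 ± 141 at 7.5 µM. WNT genes gave 11 of 14 higher and none lower (11 adjusted over the list alone; camera adjusted p = 1.23e-16, and adjusted p = 0.0147 with an estimated correlation), with SP5 at 10.30 and LEF1 at 6.21. Boundary genes gave 5 of 9 higher (6 adjusted over the list alone; camera adjusted p = 6.93e-07, and adjusted p = 0.144 with an estimated correlation), such as PAX2, a paired-box gene of the boundary (6.79). Progenitor genes gave 3 of 12 higher (3 adjusted over the list alone; camera adjusted p = 0.00313, and adjusted p = 0.0913 with an estimated correlation), VIM, an intermediate filament of progenitors, by 5.67 and the adhesion protein CDH2 by 3.03. In the dopamine neuron list 1 of 13 rose, DDC, the dopa decarboxylase (8.46), and 4 fell, such as RET, a GDNF co-receptor (−4.90). Adjusted over the list alone, 3 rose and 8 fell (camera adjusted p = 0.0238, and adjusted p = 0.177 with an estimated correlation), a list call lost without 7.5 µM replicate 1 (0.0717). GAD1 (7.38) and ZIC1 (8.32) also rose, and GBX2, a hindbrain gene also expressed in stem cells, fell by 4.10 on the log2 scale.

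SMCO3 (at least 351-fold higher, 1209 counts against 0) and GSX1, a homeobox gene (at least 169-fold), were further leading genes on the higher side. HMX2, another homeobox gene (at least 236-fold lower, 616 counts against 0), was one on the lower. POU5F1P3 (4945 counts against 1) and TDGF1P3 (1954 against 1) also led the lower side, but both are pseudogenes that can share reads with POU5F1 and TDGF1, so their values are uncertain. MKI67 stood at 298 ± 61.5 CPM against 498 ± 2.95 and did not pass (−0.74), and 0 of 15 cell cycle genes passed (camera adjusted p = 0.116). With a block within day 11, MKI67 passed (edgeR adjusted p = 0.0136). By edgeR's quasi-likelihood test 1978 of 19672 genes passed, 856 higher and 1122 lower (4601 at an unadjusted p under 0.05, 3537 by DESeq2). With the replicate number as a block within day 11 the count was 6838, 3274 higher and 3564 lower. For POU5F1 the standard error was 0.57 (edgeR adjusted p = 0.000785), for LMX1A 0.84 (0.00149) and for FOXA2 1.03 (0.00486). Without 1 of the 4 compared libraries the unblocked count was 249 to 404. The call of SHH was lost without hPSC replicate 1 (9.23) or 2 (8.14), and that of TDGF1 without 7.5 µM replicate 1 (−10.42).

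Day 11 cells at 0.7 µM were also set against hPSC. NKX2-1 had 665 counts against 0, at least 218-fold higher, and PAX6 rose by 6.95. FOXA2 rose by 8.83, LMX1A by 9.26 and SHH by 11.32, while POU5F1 fell by 8.98 on the log2 scale. MKI67 fell from 498 ± 2.95 to 91.7 ± 25.1 CPM. PTCH1, the hedgehog receptor and target, rose by 3.71.

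All 12 floor plate genes rose at 0.7 µM (12 adjusted over the list alone; camera adjusted p = 8.91e-23, and adjusted p = 0.0422 with an estimated correlation). Of 13 pluripotency genes 9 fell (10 adjusted over the list alone; camera adjusted p = 1.22e-12, and adjusted p = 0.0418 with an estimated correlation). Progenitor genes gave 4 of 12 higher (8 adjusted over the list alone; camera adjusted p = 5.48e-05, and adjusted p = 0.0422 with an estimated correlation). Cell cycle genes gave 0 higher and 5 of 15 lower (9 adjusted over the list alone; camera adjusted p = 7.15e-06, and adjusted p = 0.0766 with an estimated correlation), for example BUB1, a spindle checkpoint kinase (−3.05). SHH targets gave 4 of 8 higher (5 adjusted over the list alone; camera adjusted p = 0.000353, and adjusted p = 0.0557 with an estimated correlation). WNT genes gave 6 of 14 higher (8 and 1 adjusted over the list alone; camera adjusted p = 0.000166, and adjusted p = 0.0557 with an estimated correlation). The edgeR quasi-likelihood test called 2248 of 19672 genes, 1045 higher and 1203 lower (5589 at an unadjusted p under 0.05, 4400 by DESeq2), and 9064 with the block within day 11, 4139 higher and 4925 lower. The unblocked count was 115 to 1590 without 1 of the compared libraries. The call of MKI67 was lost without hPSC replicate 1 (−2.44) or 2 (−2.40), and those of FOXA2 (8.18) and SHH (10.93) without hPSC replicate 2. PAX6 lost its call without hPSC replicate 1 (7.94), hPSC replicate 2 (6.46) or 0.7 µM replicate 1 (6.72).

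The day 16 and day 30 tables assign reads to genes differently from the hPSC and day 11 tables. Antisense RNA genes, which made up 0.259% to 0.356% of gene counts in the 10 earlier libraries, held 32.7% to 39.8% in the 4 later ones. Protein-coding genes with no annotated gene on the other strand within 2 kb held 23.7% to 24.4% in the earlier libraries and 2.21% to 5.15% in the later ones. On the mitochondrial genome, MT-ND6, the protein-coding gene of the light strand, stood at 52.4 to 292 CPM in the earlier libraries and at 2990 to 6630 in the later ones, and MT-CYB, on the opposite strand, at 998 to 6240 and 144 to 572. Over 5493 pairs of overlapping genes on opposite strands, a later library's levels correlated with the 7.5 µM day 11 level of the gene on the other strand (Spearman's rho 0.53 to 0.6 across genes) more than with that of the gene itself (0.22 to 0.37). The fold changes that follow for these 4 libraries are those of the tables' values, not established changes of the named transcripts.

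**Figure D3:**
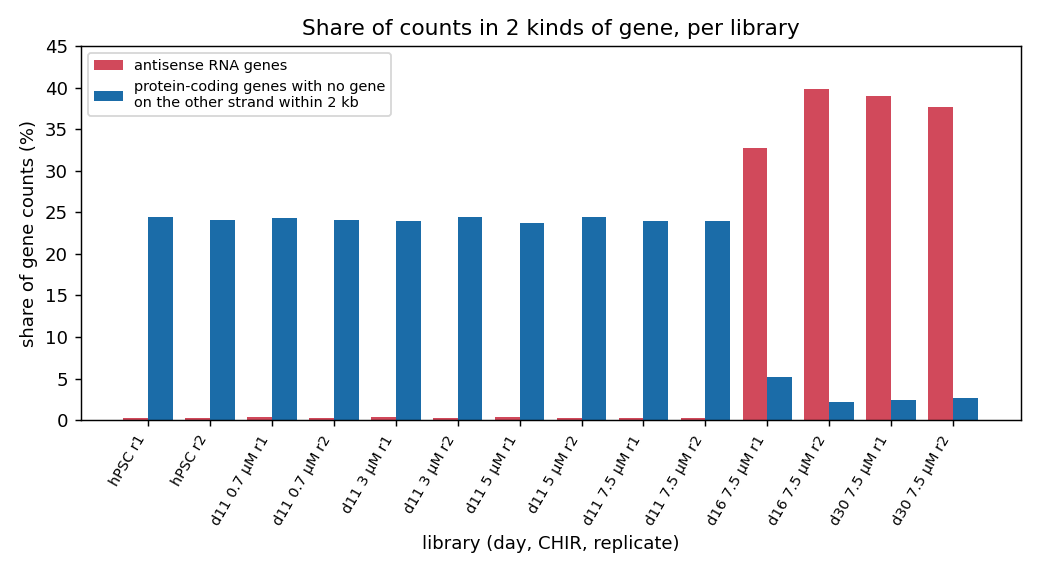
Share of gene counts (percent, axis from 0) in antisense RNA genes and in protein-coding genes with no annotated gene on the other strand within 2 kb, for each of the 14 libraries. The antisense share is under 0.36% in the 10 hPSC and day 11 libraries and 32.7% to 39.8% in the 4 day 16 and day 30 libraries.

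Day 30 was set against day 16 in tables of the same kind, to follow the maturation of the 7.5 µM cultures. Values of proliferation genes were much lower at day 30: MKI67 fell from 12.5 ± 5.03 to 0.768 ± 0.299 CPM (169 to 8 counts) and CENPF, a kinetochore protein, by 4.66 on the log2 scale. NES, the progenitor filament nestin, fell from 125 ± 9.89 to 24.4 ± 14 CPM, and OTX2 from 62.9 ± 51 to 8.70 ± 1.27. NEFL, the light neurofilament chain of neurons, rose from 34.1 ± 18.3 to 212 ± 49.8 CPM, and SYP, the synaptic vesicle protein synaptophysin, by 1.64. TH, the enzyme that makes dopamine's precursor, had 14 and 2 counts in day 16 replicates 1 and 2 and 29 and 3 at day 30 and did not pass (edgeR adjusted p = 0.353). Its difference turned to lower at day 30 without day 30 replicate 1 (−0.94).

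Of 14 cell cycle genes 0 rose and 9 fell (9 adjusted over the list alone; camera adjusted p = 1.22e-06, and adjusted p = 0.722 with an estimated correlation), such as TOP2A, a topoisomerase of dividing cells (−4.23), and CDK1 (89 counts to 1, ratio 73.8, interval 12.9 to 2950). All 4 tested Notch pathway genes fell (4 adjusted over the list alone; camera adjusted p = 0.000284, and adjusted p = 0.722 with an estimated correlation). The ligand DLL1 fell by 3.47 and the receptor NOTCH1 by 3.75. Progenitor genes gave 0 higher and 6 of 8 lower (6 adjusted over the list alone; camera adjusted p = 0.00117, and adjusted p = 0.722 with an estimated correlation). Floor plate genes gave 0 higher and 4 of 12 lower (5 adjusted over the list alone; camera adjusted p = 0.00117, and adjusted p = 0.722 with an estimated correlation), among them SHH (−3.03); LMX1A (−1.38), FOXA2 (−0.37) and EN1 (−0.90) did not pass. General neuronal genes gave 2 of 14 higher (4 and 1 adjusted over the list alone; camera adjusted p = 0.0263, and adjusted p = 0.722 with an estimated correlation). That call was lost without day 16 replicate 2 (camera adjusted p = 0.502) and stood at 2.59e-05 without day 16 replicate 1 (adjusted p = 0.86 with an estimated correlation). Day 16 replicates 1 and 2 lay far apart in STMN2 (163 and 12.8 CPM), DCX (152 and 27.4) and MAP2 (210 and 36.6), proteins of the neuronal cytoskeleton. Day 16 replicate 1 also differs from the other 3 late libraries in how reads fall on genes: 5.15% of its counts were in protein-coding genes with no gene on the other strand (2.21% to 2.66% in the others), and its antisense share was 32.7% (37.7% to 39.8%). In the dopamine neuron list 0 of 13 passed (camera adjusted p = 0.237; without day 16 replicate 1 it was 0.034, and adjusted p = 0.86 with an estimated correlation), with NR4A2 at 0.81. WNT genes gave 0 higher and 3 of 10 lower (1 and 5 adjusted over the list alone; camera adjusted p = 0.118), and PAX2 rose by 3.98.

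COL28A1, a collagen gene with no annotated gene on the other strand within 2 kb, rose from 10 to 1014 counts (6.99 with a standard error of 0.76, edgeR adjusted p = 1.39e-07). SSTR1, a somatostatin receptor, had 0 and 67 counts (at least 26.9-fold higher). WTAPP1 (2 and 4150 counts) is a pseudogene with 6 genes on the other strand within 2 kb, and its value is uncertain. By edgeR's quasi-likelihood test 1702 of 15435 genes passed, 1053 higher and 649 lower (3578 at an unadjusted p under 0.05, 1715 by DESeq2). Over the 2340 tested protein-coding genes with no annotated gene on the other strand within 2 kb, a check added after seeing the tables, 125 passed, 78 higher and 47 lower. MKI67 (−3.62), TOP2A (−3.75), COL28A1 (7.57) and PAX2 (4.28) were among them, and NES (−2.14), OTX2 (−2.30) and HES1 of the Notch list were not (edgeR adjusted p = 0.116, 0.0539 and 0.0581). Within this set 4 of 8 cell cycle genes fell (8 adjusted over the list alone; camera adjusted p = 3.96e-10, and adjusted p = 0.541 with an estimated correlation). Genes of this kind held only 2.21% to 5.15% of counts in the later libraries, against 23.7% to 24.4% in the earlier ones. The check thus leaves out overlapping genes. It does not show that the remaining values, that of COL28A1 included, come from the genes' own transcripts.

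The count of 1702 was 39 without day 30 replicate 1, 261 without day 30 replicate 2, 4386 without day 16 replicate 1 and 8078 without day 16 replicate 2. MKI67 (−4.38 and −3.70), TOP2A (−4.20 and −4.26), OTX2 (−2.94 and −2.80), SYP (1.56 and 1.72), SHH (−3.01 and −3.04), NOTCH1 (−3.48 and −4.06) and PAX2 (3.66 and 4.23) lost their calls without either day 30 library, and NEFL (2.43), NES (−1.81) and SSTR1 without day 30 replicate 1. LMX1A passed as lower without day 16 replicate 2 (−1.72) and NR4A2 as higher without day 16 replicate 1 (2.20). In simulated data for this comparison the test called 12 of 100 genes changed 4-fold and 0 of 100 changed 2-fold.

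Day 16 against day 11 at 7.5 µM crosses from the one kind of count table to the other, so stage and table cannot be told apart and no value of this comparison can be read as a change of the cells. Some genes that dividing and neural cells use at high levels had no count at day 16. CALM2, calmodulin, had 54987 counts at day 11 and 0 at day 16 (at least 1130-fold lower), HNRNPA1, a splicing factor, 72637 and 0, and SOX2 14403 and 0. They had no count at day 30 either. MKI67 and NES, like CALM2 and SOX2 without an annotated gene on the other strand within 2 kb, kept counts at day 16 (MKI67 127 and 42, NES 1050 and 559). The cause of the zeros was not tested. TUBB3 (ENSG00000258947), which rises as neurons form, had 1480 and 0. Another entry with that symbol, ENSG00000198211, is not included in these counts. On the higher side BCL2L14, a BCL2 family member, had 0 and 10245 counts (at least 55500-fold higher if the TMM scaling holds). CNGB3, a photoreceptor channel subunit, had 0 and 6666, and the mitochondrial tRNA genes MT-TS1 and MT-TP 0 and 10363 and 0 and 6706. All bounds and fold changes of this comparison carry the TMM scaling between the 2 kinds of count table, which is itself uncertain. LMX1A passed as higher (1.70) and FOXA2 as lower (−1.58), the latter not without day 11 replicate 1 (−1.42) or 2 (−1.87). The raw counts of LMX1A were 3427 and 3825 of 33.67 and 32.08 M at day 11. At day 16 they were 1201 and 362 of 6.34 and 5.41 M, so its value rests on that scaling.

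By edgeR's quasi-likelihood test 13373 of 19180 genes passed between day 11 and day 16, 7550 higher and 5823 lower (13913 at an unadjusted p under 0.05, 12243 by DESeq2). Cell cycle genes gave 14 of 15 lower (14 adjusted over the list alone; camera adjusted p = 0.00126, and adjusted p = 0.592 with an estimated correlation), and general neuronal genes 13 of 15 higher and 1 lower (13 and 1 adjusted over the list alone; camera adjusted p = 0.0805; without day 16 replicate 2 it was 0.00632, and adjusted p = 0.423 with an estimated correlation). Dopamine neuron genes gave 9 of 13 higher (9 adjusted over the list alone; camera adjusted p = 0.0996; without day 16 replicate 2 it was 0.0249, and adjusted p = 0.423 with an estimated correlation). WNT genes gave 3 of 14 higher and 10 lower (camera adjusted p = 0.0198), pluripotency genes 4 of 4 lower (0.0376) and p53 targets 1 of 12 higher and 8 lower (0.0376), each with adjusted p = 0.592 with an estimated correlation. These 3 calls were lost without day 16 replicate 1 (camera adjusted p = 0.0799 each). FGF feedback genes gave 8 of 9 lower (8 adjusted over the list alone; camera adjusted p = 0.0198, and adjusted p = 0.592 with an estimated correlation). NPM1P27, a pseudogene that can share reads with NPM1, had 30455 counts at day 11 and 0 at day 16, a value that is uncertain for that reason as well.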

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

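The predictions for the tests on the day 11 replicates and on the 7.5 µM count were written after these patterns had been seen but before the tests were run, and the tests on the later tables were chosen after their results had been seen.

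In data the report does not otherwise use, reads mapped to more than 1 place made up 28.34% of the total in 3 µM replicate 1 and 27.59% in 5 µM replicate 1, against 24.96% and 17.84% in 0.7 µM replicates 1 and 2. It was 17.22% in 3 µM replicate 2, 17.64% in 5 µM replicate 2, and 17.4% and 15.13% in 7.5 µM replicates 1 and 2, so in all 4 arms the share was higher in replicate 1, while in hPSC it was 15.38% and 16.07%. Reads counted to no gene made up 44.15% and 43.99% in 3 µM replicates 1 and 2 and 44.27% in 5 µM replicate 1, against 42.96% and 41.45% at 0.7 µM. It was 39.0% in 5 µM replicate 2, 38.63% and 37.41% at 7.5 µM, and 40.02% and 44.33% in hPSC, the last being the highest of all.

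At day 11, replicates 1 and 2 differ in the same genes in all 4 arms, with 10401 of 18709 genes passing in the replicate term. A different oxygen supply in culture might account for part of this: 9 of the 10 hypoxia and glycolysis genes passed, all higher in replicate 2, as that explanation predicted. Gene length took 14.3% of the variance of the difference, and histone transcripts without a poly(A) tail, a sign of RNA selection, had a median difference of −0.61, both between their set limits, so neither can be told. Uniquely mapped reads outside annotated genes also split by replicate number, at 10.97% to 14.07% in replicate 1 and 17.24% to 21.9% in replicate 2. Technical differences between the libraries thus remain open too, and a biological difference between the batches of cultures remains open and untested.

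Far more genes pass at 7.5 µM than at 5 µM against 0.7 µM. If 7.5 µM replicate 1, which shares its batch only in part, were the likely cause, the ratio of the counts without replicate 1 of each boosted arm would be under 1.5, and it was 36.4. Depth predicted the same after thinning all libraries to 20.52 M, where the ratio was 9.56. The first ratio compares separate fits, and 7.5 µM replicate 1 still entered the spread estimate of the fit without 5 µM replicate 1. It therefore cannot decide on the batch explanation. The depth test does not favour its explanation, and a stronger response to the higher dose remains open and untested.

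At day 16 and day 30, antisense RNA genes hold 32.7% to 39.8% of the counts. Counting of reads on the strand opposite to their gene might explain this: the levels followed the gene on the other strand with a Spearman correlation of at least 0.53, above the highest with the gene itself (0.37). Counting without regard to strand predicted that genes with no gene on the other strand would keep at least 0.5 of their share, and they held at most 5.15% against 23.7% to 24.4%. The later stage of the cells predicted a median within 4-fold for such genes with at least 50 CPM in every earlier library. The median log2 ratio was −3.86, and 462 of 475 fell by over 4-fold. For these genes the values argue against counting without regard to strand and against the later stage. Of the explanations tested, counting on the wrong strand is the one these values go with. The library kit and the counting options are not named, so its origin is not known and it stays a hypothesis.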

How the results depend on the processing

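The block fits' alternatives, the gene set without opposite-strand genes and the crossed pairing are tests chosen after results were seen; the other tests were planned.

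No result that was called turned its direction and stayed called, though lists and genes that were not called did turn when 1 library was left out, for example TH at day 30 against day 16 (−0.94 without day 30 replicate 1). Causes were not tested, apart from settings that by construction use fewer genes or libraries. Counts of genes that pass, without the replicate block and then with it, were as follows; where a library is left out, the lone sample is assumed to vary like the other groups. For 7.5 against 0.7 µM, 0 became 29 with no filter, 657 by DESeq2, 1967 with the block and 13 with the hPSC libraries, and 1967 became 3391 with no filter, 3006 by DESeq2 and 2991 with the hPSC libraries (754 to 5613 with 1 library left out). For 5 against 0.7 µM, 0 became 6 with no filter, 129 by DESeq2 and 211 with the block, and 211 became 783, 612 and 372 in the same order of settings (50 to 179). For 3 against 0.7 µM, 0 became 17 by DESeq2 and 4 with the block, and 4 became 320, 196 and 16 (0 to 59). For 5 against 3 µM, 0 with the block became 74 with no filter and 33 by DESeq2 (0 to 1). For 7.5 against 5 µM, 0 became 203 by DESeq2 and 1221 with the block, and 1221 became 3136, 2777 and 2554 (5 to 5828).

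The slope over concentration gave 25, and 5 with a strict filter, 330 by DESeq2, 222 with the block, 67 on a linear scale and 0 without the 7.5 µM arm (0 to 29 with 1 library left out). With the block, 222 became 383 with no filter, 112 with a strict filter, 812 by DESeq2 and 919 without the 7.5 µM arm (2 to 251). For 0.7 µM against hPSC, 2248 became 4400 by DESeq2, 5282 with the replicate number as a block, 9064 with the block within day 11 and 1143 on the 4 compared libraries only (115 to 1590; 5836 to 7446 with the block within day 11). For 7.5 µM against hPSC, 1978 became 3537, 3987, 6838 and 5500 (249 to 404; 4023 to 8432). For day 30 against day 16, 1702 became 994 with a strict filter, 1067 with the block and 125 over genes with no gene on the other strand (39 to 8078), and crossing the replicate numbers gave 1749. Day 16 against day 11 stayed within 1.5 times of 13373 throughout (10729 to 18475), with 13053 under the block.

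Lists called fell with an estimated correlation: with the block, from 13 to 0 at 7.5 µM, 15 to 0 at 5 µM and 13 to 0 at 3 µM, and without it from 13 to 9 for the slope, 9 to 3 and 11 to 3 against hPSC, and 5 to 0 in each later comparison. That form also rests on the residual degrees of freedom, 3 in these blocked fits, 6 for the slope, 5 against hPSC, and 2 and 3 later. Correlation between genes and few libraries therefore cannot be told apart as the reason. The block and RLE scaling moved no count of lists by over 1.5 times. Leaving out 1 library moved it that far in 10 cases and not in 70. Of the calls of named genes, 188 were kept with RLE scaling and 1 was lost, and by DESeq2 186 were kept and 3 lost. With the replicate block added 92 were kept and 4 lost, and with the block taken away all 93 were lost. Leaving out 1 library kept 527 and lost 262. Among named genes that were not called, 9 gained a call by DESeq2, 3 with the block added and 15 with 1 library left out, and 36, 10 and 176 stayed uncalled. At 5.41 to 6.34 M the simulated test for day 30 against day 16 found 12 of 100 genes changed 4-fold. At day 11 (20.5 to 44.8 M) the simulated pairwise dose comparisons found 0 of 100 without the block and 83 to 92 with it. The fits differ in libraries and spread as well as depth, so depth is not shown to be the limit.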

Other observations

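The tests of gene groups below used lists fixed beforehand, but applying them to the replicate number, and the choice of genes on the other strand, came after results were seen.

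Of the lists not yet given for 7.5 against 0.7 µM at day 11, those that follow were not called by camera with the block. In the neural crest list 1 of 7 genes rose and 2 fell (2 and 2 adjusted over the list alone; camera adjusted p = 0.407), among them NGFR, the low-affinity nerve growth factor receptor, from 294 ± 2.29 to 105 ± 50.3 CPM. Mesenchymal and vascular genes gave 2 of 8 higher and 1 lower (3 and 1 adjusted over the list alone; camera adjusted p = 0.519), such as PDGFRB, a pericyte receptor (1.53). Choroid plexus genes gave 1 of 5 higher (2 and 1 adjusted over the list alone; camera adjusted p = 0.631), and glial genes 1 of 6 lower (1 and 3 adjusted over the list alone; camera adjusted p = 0.312). SHH targets gave 1 of 8 higher and 2 lower (1 and 3 adjusted over the list alone; camera adjusted p = 0.0645).

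Between the replicate numbers at day 11, 5372 genes were higher and 5029 lower in replicate 2 by edgeR's test of the replicate term. Hypoxia genes differed most (median log2 difference 2.08; camera adjusted p = 6.55e-05, and adjusted p = 0.517 with an estimated correlation), such as EGLN3 (2.41) and the angiogenic factor VEGFA (2.28). P53 targets gave 9 of 12 higher and 2 lower (camera adjusted p = 0.177), for example GDF15, a stress-induced cytokine (2.18). General neuronal genes gave 8 of 15 higher, such as STMN2, a protein of growing axons (1.16). FOXA2 was among 4 of 12 floor plate genes lower in replicate 2 (−1.05).

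For day 30 against day 16, values of genes that lie opposite a list member were LEF1-AS1 −3.85 (edgeR adjusted p = 0.000283), VIM-AS1 −1.48 (edgeR adjusted p = 0.0492) and FEZF1-AS1 3.07 (edgeR adjusted p = 0.0414).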
